A study of Mus musculus with 8 samples.

How the data were processed

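Mouse J1 embryonic stem cells (129Sv/J), grown without feeder cells in serum and LIF, carried a double reporter of the 2-cell-like state, a rare state in such cultures in which genes of the 2-cell embryo are transcribed. The cells had been infected with a non-targeting short hairpin RNA (shNT) or one against eIF4A2 (sheIF4A2), selected with drug and sorted into double positive (DP) and double negative (DN) cells. Total RNA was extracted with Trizol, and polyA-selected libraries were sequenced as paired 150 bp reads, per the labels. There were 8 libraries in 4 groups of 2 (shNT DN, shNT DP, sheIF4A2 DN and sheIF4A2 DP). The groups were taken from the sample descriptions and the replicate numbers from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The promoters of the reporters are not named, so 2-cell genes cannot be treated as independent of the sort gate.

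The authors named Bowtie2 2.3.4.3, SAMtools 1.9, HTSeq 0.11.2, edgeR 3.26.8 and the genome build mm9. Bowtie2 does not split reads over introns, no spliced aligner is among the named tools, and the role of each tool was not stated. The expression values deposited by the authors were counts per 1e6 reads (CPM) of the library size after TMM scaling. Each library's values were whole multiples of 1 constant, so whole reads were recovered for 100% of values (tolerance 1e-06 reads). The table also held log2 fold changes made by the authors, and adjusted p-values (FDR) of their likelihood ratio test, deposited for 6 pairs of groups. That FDR had been adjusted over 37310 genes, of which 31021 were listed (1 identifier stood in the table again). Values computed here and values from the authors' table are named separately wherever both appear. Symbols were matched through the deposited table, GENCODE M21 and RefSeq synonyms. These references use a later genome build than mm9, so no coordinates are given.

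Recovered reads per library, in units of 1e6, were between 2.87 and 4.65. The percentage of even counts among genes with 20 to 199 reads lay between 49.7 and 50.5. Counting both mates of every pair as separate reads would have left an excess of even counts. Separate counting cannot be excluded if many mates were lost, since the excess would then vanish. Between replicates, the chi-square per degree of freedom was 1.93 to 3.16 over genes with at least 20 reads, and Pearson's r of log2 values was 0.975 to 0.983 across genes, which are not independent replicates. shNT DP replicate 2 stood apart from the other libraries, with 17261 genes detected and 548 genes at exactly 1 read, against 17605 to 18553 genes and 1079 to 1478 at 1 read in the others. The share of reads on mitochondrial genes was 1.85 to 2.24% in shNT and 2.54 to 3.08% in sheIF4A2 libraries. Ribosomal protein genes (76 measured) took 0.388 to 0.442% of reads, a small share for transcripts that are usually abundant in polyA-selected RNA. Loss of reads over introns was not tested as the reason, and the levels of these genes are uncertain. How polyA selection bears on the counts of replication histones was not tested either, so their levels are uncertain as well. Genes of multi-copy families (Zscan4, Usp17l, Eif1ad, Pramel, Tdpoz, histones) and genes with processed pseudogenes, such as H3f3a, are counted with more uncertainty than single-copy genes, since how reads with several matches were handled was not stated.

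Differential expression was tested with limma 3.58.1 (limma-trend) in R 4.3.3, on log2(CPM + 1), over 16631 genes with at least 1 CPM in at least 2 libraries. All 8 libraries were fitted with 1 mean per group and no replicate block, with 4 degrees of freedom among libraries. The 5 contrasts were DP against DN within each shRNA, sheIF4A2 against shNT within each subpopulation, and the interaction. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and genes with adjusted p under 0.05 are called higher or lower. The first choice of the design had been edgeR on counts. Because the table held CPM, limma-trend took its place, as the design allowed, and edgeR 4.0.16 (quasi-likelihood) on the recovered reads was an added alternative. It called 545 genes higher and 259 lower for DP against DN in shNT, 2018 and 2143 for DP against DN in sheIF4A2, 2441 and 2648 for sheIF4A2 against shNT in DP, 1609 and 1574 in DN, and 753 and 1018 for the interaction. Unless stated otherwise, levels are mean CPM ± SD (n = 2 libraries), and log2 differences are ± standard error of the limma fit. Folds and ratios between groups are of pooled reads, summed over the libraries of a group per summed library size. They can differ from the ratio of the mean CPM, most at few reads. A fold against a group with no read is a lower bound from a floor of 3 reads over the group. With 1 to 3 reads, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

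There were 19 gene lists, fixed before the data were examined together with the contrasts, the rule for named genes and most of the alternative settings. They held genes of the 2-cell state, naive pluripotency, formative and primed pluripotency, extraembryonic endoderm, mesoderm, neuroectoderm, trophoblast, fibroblasts or feeder cells, the germline, translation initiation, histone H3.3 and its chaperones, repressors of the 2-cell state, the integrated stress response, p53 targets, the interferon response, ribosomal proteins, glycolysis, the cell cycle and replication histones. Of 50 listed 2-cell genes, 35 were matched and 31 measured. Lists were tested with camera (limma) at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 19 lists of a contrast. A further 4 lists (hypoxia targets, BMP and SMAD targets, NODAL targets, heat shock) were added after the values had been seen. Named genes were Eif4a2, Eif4a1, H3f3a and H3f3b; per contrast the 5 largest rises and 5 largest falls among called genes with at least 1 CPM and with groups that did not overlap (for the interaction, by adjusted p and mean CPM only); and per list up to 4 members with the smallest p, or 6 for the 2-cell list. Members of these sets were left out where space required, and genes outside of them are said to be so.

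The calling procedure was tested on simulated data at these depths and group sizes, with planted changes in 66 or 67 genes per fold and contrast. It recovered 75.8 to 84.8% of 4-fold, 44.8 to 52.2% of 2-fold and 25.4 to 37.3% of 1.5-fold changes, with 3 to 14 false calls among 16143 to 16185 genes. Most contrasts called far more genes than were planted, which loosens the adjusted threshold, so the rates there may differ. Alternatives covered the scaling, the filter, the pseudocount, the tool (DESeq2 1.42.0, limma-voom, edgeR), the libraries in the fit, a replicate block, each library left out in turn, thinning of reads, and removal of a trend with GC content and transcript length, for which 100% of tested genes had a value. Groups of 2 are too small for a test of single outlying libraries or for regrouping of samples, and neither was run. Translation was not measured in these libraries.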

Results

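The series asks how the translation initiation helicase eIF4A2 bears on developmental potency and on histone H3.3. RNA levels were measured in J1 mouse embryonic stem cells that had been infected with shNT or sheIF4A2 and sorted by a double reporter of the 2-cell-like state into DP and DN cells, with 2 libraries in each of the 4 groups. The depth in units of 1e6 reads was 3.96 and 4.65 in shNT DN, 4.24 and 4.33 in shNT DP, 3.02 and 2.87 in sheIF4A2 DN, and 3.10 and 3.14 in sheIF4A2 DP. Every sheIF4A2 library was thus shallower than every shNT library, and the labels give no batch, so a difference in library preparation cannot be told apart from the shRNA.

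The targeted transcript was lower in only 1 of the subpopulations. Eif4a2 stood at 941 ± 12.3 CPM in shNT DN and 601 ± 5.80 CPM in sheIF4A2 DN, 0.639-fold (log2 difference -0.65 ± 0.05, adjusted p = 9.65e-11), with both sheIF4A2 libraries below both shNT libraries. In DP cells it stood at 1033 ± 8.22 CPM with shNT and 1018 ± 49.7 CPM with sheIF4A2 (-0.02 ± 0.05, adjusted p = 0.787). The interaction was 0.62 ± 0.07 (adjusted p = 7.79e-07). With a trend in GC content and transcript length removed, the difference in DP became -0.24 (adjusted p = 6.28e-04). Because Eif4a2 was not called lower in these cells without that correction, they are called the DP libraries labelled sheIF4A2, and their differences from shNT are not read as following from a lower Eif4a2 transcript. Eif4a1, the paralog of Eif4a2, stood at group means of 428 to 475 CPM and was called in no contrast.

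Of the H3.3 genes, H3f3b stood at 599.8 CPM in shNT DN, 545 ± 14.8 in shNT DP, 534 ± 33.7 in sheIF4A2 DN and 631 ± 12.6 in the DP libraries labelled sheIF4A2. It was 0.21 ± 0.06 higher in DP with sheIF4A2 than with shNT (adjusted p = 0.00738) and 0.24 ± 0.06 higher in DP than in DN of sheIF4A2 (adjusted p = 0.00287). These differences were 0.03 (adjusted p = 0.790) and 0.01 (adjusted p = 0.938) once the trend in GC content and transcript length was removed, which also took the interaction from 0.38 ± 0.08 (adjusted p = 0.00311) to 0.21 (adjusted p = 0.0989). Without replicate 2 of these DP libraries, the adjusted p of the 3 values was 0.0974, 0.0674 and 0.0577; without shNT DP replicate 1 the first was 0.0798, and without sheIF4A2 DN replicate 1 the second was 0.0690. For DP against DN in shNT, H3f3b was at -0.14 ± 0.06 (adjusted p = 0.262), and at -0.20 with that trend removed (adjusted p = 0.0486), while the authors' table had it higher in DN by 0.14 (FDR 0.0273). In DN, H3f3b was -0.17 ± 0.06 with sheIF4A2 (adjusted p = 0.0495). That call was lost with edgeR (adjusted p = 0.0740) and without any 1 library other than sheIF4A2 DN replicate 2, with a smaller difference of -0.10 without sheIF4A2 DN replicate 1 (adjusted p = 0.385) and -0.14 without shNT DN replicate 1 (adjusted p = 0.304), and -0.20 without shNT DN replicate 2 (adjusted p = 0.0882). Leaving out a DP library kept -0.17 and moved only the adjusted p, to 0.0649 to 0.0893. H3f3a, which has processed pseudogenes, was counted at 25.7 ± 1.87, 31.1 ± 0.931, 23.3 ± 7.91 and 38.8 ± 0.804 CPM in the same order of groups. It was called only for DP against DN of sheIF4A2 (0.75 ± 0.20, adjusted p = 0.00561), and not without sheIF4A2 DN replicate 1 (0.41, adjusted p = 0.206) or either of the DP libraries labelled sheIF4A2 (adjusted p = 0.0735 and 0.0912).

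**Figure D1:**
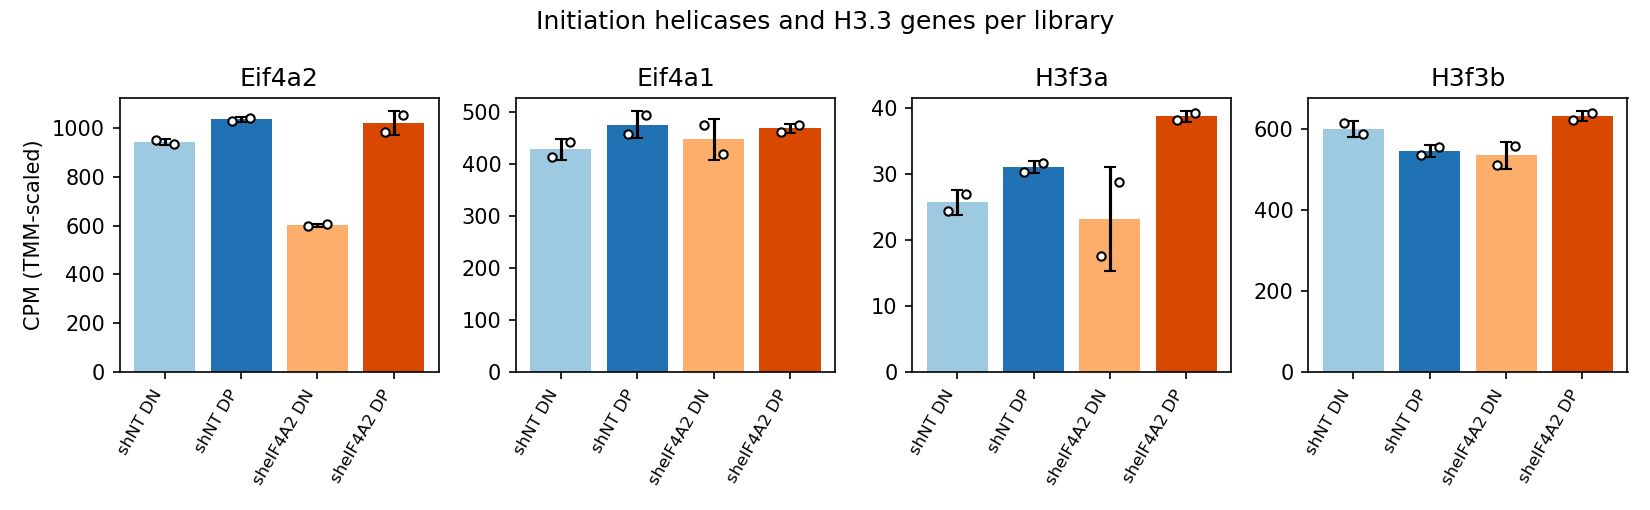
Levels of Eif4a2, Eif4a1, H3f3a and H3f3b in CPM (linear axes from 0) for each of the 8 libraries, by group; points are libraries and bars their mean. Eif4a2 was near 601 CPM in sheIF4A2 DN against 941 to 1033 CPM in the other groups' means.

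DP and DN cells of the shNT control show which transcripts mark the reporter-positive state. Zscan4d, of the Zscan4 family of the 2-cell embryo, rose from 0.244 ± 0.345 CPM in DN to 94.3 ± 3.41 CPM in DP, a ratio of 421 from pooled reads with a counting interval of 116 to 3486. Gm4340 was not seen in DN and stood at 83.3 ± 4.85 CPM in DP, at least 248-fold higher. Usp17le, of a deubiquitinase family, rose 84.7-fold by pooled reads to 56.9 ± 5.19 CPM, and Eif1ad8 and Eif1ad3 rose to 55.1 ± 6.10 and 39.3 ± 0.958 CPM. Of the 31 measured 2-cell genes, 26 rose, 0 fell and 5 did not pass (28 rose when adjusted over the list alone), with a median log2 difference of 2.73, or 3.51 with genes absent from a group at their bound. Camera gave adjusted p = 4.34e-82, and adjusted p = 9.61e-04 with an estimated correlation. Because the reporters mark the 2-cell-like state, these genes describe the sort gate. The largest falls, in Ppp1r3d (-1.82 ± 0.43), Romo1 (-1.78 ± 0.46), Adra2a (-1.77 ± 0.44), Podn (-1.76 ± 0.51) and Susd3 (-1.72 ± 0.48), were of transcripts at or under 7.20 CPM, and none of the 5 was called without shNT DN replicate 1 or 2, shNT DP replicate 2, or either of the DP libraries labelled sheIF4A2. Without shNT DP replicate 2, the library that stood apart from the others, the falls were smaller, at -1.14 for Ppp1r3d (adjusted p = 0.301), -1.16 for Romo1 (0.389) and -0.97 for Adra2a (0.428).

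Other gene groups moved less in shNT. Of 30 naive pluripotency genes, 6 rose and 2 fell (12 and 3 adjusted over the list alone), with Nanog, a core pluripotency factor, at 930 ± 35.4 CPM in DN and 1297 ± 5.20 in DP (0.48 ± 0.05, adjusted p = 1.42e-07) and Fbxo15 and Dppa2 up by 1.20 ± 0.13 and 0.81 ± 0.10. The list passed camera (adjusted p = 9.95e-04), but not with an estimated correlation (adjusted p = 0.121). In extraembryonic endoderm, 4 of 17 rose (6 adjusted over the list alone), among them the laminin gene Lamc1 (0.52 ± 0.07) and the lipoprotein gene Apoe (0.45 ± 0.06), with adjusted p = 0.00207 for the list and adjusted p = 0.292 with an estimated correlation. This list was not called without shNT DN replicate 1 (adjusted p = 0.0596) or shNT DP replicate 1 (adjusted p = 0.0680), nor was the germline list without the latter (adjusted p = 0.0646). In the germline list 2 of 19 rose, Tex19.1 (0.99 ± 0.10) and Dazl (0.69 ± 0.11), against 5 risen and 1 fallen adjusted over the list alone. For the list as a whole, adjusted p = 0.00247, and adjusted p = 0.265 with an estimated correlation. Of 23 integrated stress genes, Slc7a5 and Chac1 rose by 0.33 ± 0.07 and 1.17 ± 0.30, but neither was called without any 1 of the shNT libraries, with adjusted p up to 0.106 for Slc7a5 and 0.194 for Chac1, both without shNT DN replicate 1 (7 adjusted over the list alone; adjusted p = 1.62e-05, and adjusted p = 0.218 with an estimated correlation). Among 25 cell cycle genes 6 rose, such as the topoisomerase gene Top2a (0.39 ± 0.07), against 9 risen and 3 fallen adjusted over the list alone. By camera the group had adjusted p = 0.0213, and adjusted p = 0.218 with an estimated correlation. Cell cycle genes were not called as a list without shNT DN replicate 2 (adjusted p = 0.190), shNT DP replicate 1 (0.0646) or shNT DP replicate 2 (0.0595), or with the trend in GC content and length removed (0.0598).

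Lists with no camera call in shNT still held single called genes. Mga, a subunit of a Polycomb complex and 1 of 27 listed repressors of the 2-cell state, stood at 1265 ± 15.0 CPM in DN and 958 ± 6.61 in DP (-0.40 ± 0.05, adjusted p = 9.97e-06); in that list 1 rose and 2 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.491). H2ax rose from 715 ± 9.82 to 1101 ± 65.5 CPM (0.62 ± 0.06). It was the 1 called of 21 genes in the replication histone list, which also holds the histone variants H2ax and H2az1 (list adjusted p = 0.359). Of 24 initiation factors 3 rose, such as Eif2s2 (0.47 ± 0.08), and 1 fell, Eif4b (-0.26 ± 0.06), the same counts as adjusted over the list alone (list adjusted p = 0.359). Of 14 H3.3 and chaperone genes, Ubn1 fell by 0.51 ± 0.10, and the falls of Ubn1 and Eif4b were not called without shNT DN replicate 1 (adjusted p = 0.0742 and 0.138) or shNT DP replicate 2 (0.0990 and 0.189; list adjusted p = 0.359). Called counts of risen and fallen genes were 1 and 0 of 14 formative genes, 0 and 0 of 13 mesoderm, 1 and 0 of 12 neuroectoderm, 1 and 0 of 15 trophoblast, 1 and 1 of 20 p53 target, 1 and 0 of 9 interferon, 0 and 1 of 76 ribosomal protein and 1 and 2 of 20 glycolysis genes. Adjusted over the list alone these were the same, save 2 and 0 formative, 3 and 1 p53 target and 0 and 0 ribosomal protein genes. Median, mean and test did not share a sign for formative, mesoderm, p53 target, interferon, glycolysis and histone genes, as for histones with a median of -0.07 and a mean of 0.12. Of the fibroblast or feeder markers, Fn1 stood at 652 CPM in DN and 623 in DP of these feeder-free cells, and the others at or under the 28.3 CPM of Pdgfrb in DN, with Thy1 at 11.9 ± 0.648 CPM in DN and 24.5 ± 4.53 in DP, the 1 called of 9. Thy1 was not called without shNT DN replicate 1 (adjusted p = 0.117), shNT DN replicate 2 (0.0619), shNT DP replicate 2 (0.211), or replicate 1 or 2 of the DP libraries labelled sheIF4A2 (0.0593 and 0.0583), and Eif4b not without either of the last (0.0531 and 0.0529). In all, limma called 367 genes higher and 158 lower in DP (2477 at an unadjusted p under 0.05), of which 117 and 12 differed by at least 1 log2 unit. Without 1 library the counts were 193 and 35 (shNT DN replicate 1), 209 and 46 (shNT DN replicate 2), 199 and 100.0 (shNT DP replicate 1) or 162 and 25 (shNT DP replicate 2). They were 209 and 55 or 206 and 54 without replicate 1 or 2 of the DP libraries labelled sheIF4A2. The authors' table gave 519 higher and 276 lower at FDR under 0.05, and listed Eif4a2 as lower in DN than in DP by a log2 value of -0.14 (FDR 2.68e-07), where limma gave 0.14 ± 0.05 for DP against DN (adjusted p = 0.184) and limma-voom adjusted p = 0.00905.

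With sheIF4A2, 2-cell genes reached higher levels in DP than they did with shNT. Zscan4d stood at 9.67 ± 0.397 CPM in DN and 2088 ± 8.21 CPM in DP, 216-fold higher. Eif1ad8 and Eif1ad3 rose 201-fold and 202-fold, to 724 ± 7.55 and 464 ± 10.6 CPM, and Zscan4c rose 142-fold to 605 ± 0.908 CPM. P4ha2, a collagen prolyl hydroxylase in the 2-cell list, rose 14.8-fold, from 29.4 ± 0.253 to 433 ± 25.8 CPM. Of 31 2-cell genes, 30 rose, 0 fell and 1 did not pass (31 adjusted over the list alone), with a median of 5.29, or 5.64 with bounds. The list test returned adjusted p = 4.58e-55, and adjusted p = 0.00215 with an estimated correlation. Low transcripts led the falls: Has2, a hyaluronan synthase, went from 6.05 ± 0.973 to 0.159 ± 0.225 CPM (-2.61 ± 0.48), Hhat fell by 2.36 ± 0.45, Tnfrsf18 by 2.03 ± 0.38, Podnl1 by 2.03 ± 0.44 and Sowaha by 2.02 ± 0.41.

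Genes of the replication histone list, variants included, rose in this comparison. Of 21 measured, 12 rose and 0 fell (13 adjusted over the list alone), among them H2ax (393 ± 37.5 to 899 ± 22.5 CPM, 1.19 ± 0.06) and the linker histone H1f2 (43.5 ± 3.90 to 131 ± 2.29 CPM, 1.57 ± 0.13), with adjusted p = 8.37e-07 and adjusted p = 0.0402 with an estimated correlation. Formative genes fell, 8 of 14 with 1 risen in both adjustments: Otx2 by 1.29 ± 0.19 and the DNA methyltransferase Dnmt3a by 0.56 ± 0.08, while Sox3 rose by 2.28 ± 0.24. As a group they had adjusted p = 0.00103, and adjusted p = 0.238 with an estimated correlation. Naive pluripotency genes went both ways, 9 up and 14 down of 30 (10 and 14 adjusted over the list alone; adjusted p = 0.0659, but 0.0391 without sheIF4A2 DN replicate 1 and 0.0342 without replicate 2 of the DP libraries labelled sheIF4A2, 0.0143 with the trend in GC content and length removed, 0.0249 without a filter and 0.0388 with library size only). In that list Fbxo15 rose by 2.92 ± 0.13 and Nanog by 0.83 ± 0.05, while Utf1 fell by 1.23 ± 0.06 and Tet1, a 5-methylcytosine dioxygenase, by 0.90 ± 0.05. Of 20 p53 targets 7 rose and 2 fell (7 and 3 adjusted over the list alone), Pmaip1, an apoptosis gene, by 2.25 ± 0.11. Camera gave adjusted p = 0.00596, and adjusted p = 0.238 with an estimated correlation. The integrated stress list had 8 up and 2 down of 23 (9 and 2 adjusted over the list alone), with Ppp1r15a up by 1.54 ± 0.13. For the list as a whole, adjusted p = 0.00596, and adjusted p = 0.294 with an estimated correlation. In the germline list 6 of 19 rose (7 adjusted over the list alone), with Dazl up by 2.20 ± 0.11. By camera the group had adjusted p = 0.00596, and adjusted p = 0.280 with an estimated correlation.

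Glucose transporter Slc2a3 rose from 2412 ± 58.7 to 4569 ± 76.9 CPM (0.92 ± 0.04), while the 20 glycolysis genes went both ways, with 5 up and 4 down. Mga fell from 742 ± 20.8 to 418 ± 21.3 CPM and Zfp809 rose by 1.91 ± 0.14 among 27 repressors of the 2-cell state, of which 6 rose and 8 fell (6 and 9 adjusted over the list alone). Initiation factors had 8 up and 4 down of 24, with Eif4a2 up by 0.76 ± 0.05 (adjusted p = 1.3e-12), Eif4g2 up by 0.43 ± 0.05 and Eif4b down, at -0.48 ± 0.06. The H3.3 and chaperone list had 3 up and 5 down of 14 (3 and 7 adjusted over the list alone). Feeder markers rose in 3 of 9, Thy1 from 11.3 ± 0.811 to 46.8 ± 2.17 CPM, Fbn1 to 11.4 ± 0.355 and Col1a2 to 3.16 ± 0.422 CPM (list adjusted p = 0.198). Counts risen and fallen were 4 and 0 of 17 in extraembryonic endoderm, 2 and 1 of 13 in mesoderm, 2 and 1 of 12 in neuroectoderm, 3 and 1 of 15 in trophoblast, 2 and 1 of 9 interferon, 3 and 2 of 76 ribosomal protein and 7 and 10 of 25 cell cycle genes. Adjusted over the list alone only ribosomal protein genes differed, with 1 and 1. By camera the extraembryonic endoderm list had adjusted p = 0.169, and adjusted p = 0.04999 with the trend in GC content and length removed. For the repressors the median was -0.02 and the mean 0.04. Over all genes, limma called 2357 higher and 2061 lower, with 1445 and 1301 without replicate 1 and 1385 and 1262 without replicate 2 of the DP libraries labelled sheIF4A2. The authors' table gave 1999 and 1704. Of the genes called in shNT, 272 of the 367 higher and 82 of the 158 lower were called the same way here. Independent lists would share 52.0 and 19.6, a loose reference since both sets of calls share the estimated spread of each gene.

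**Figure D2:**
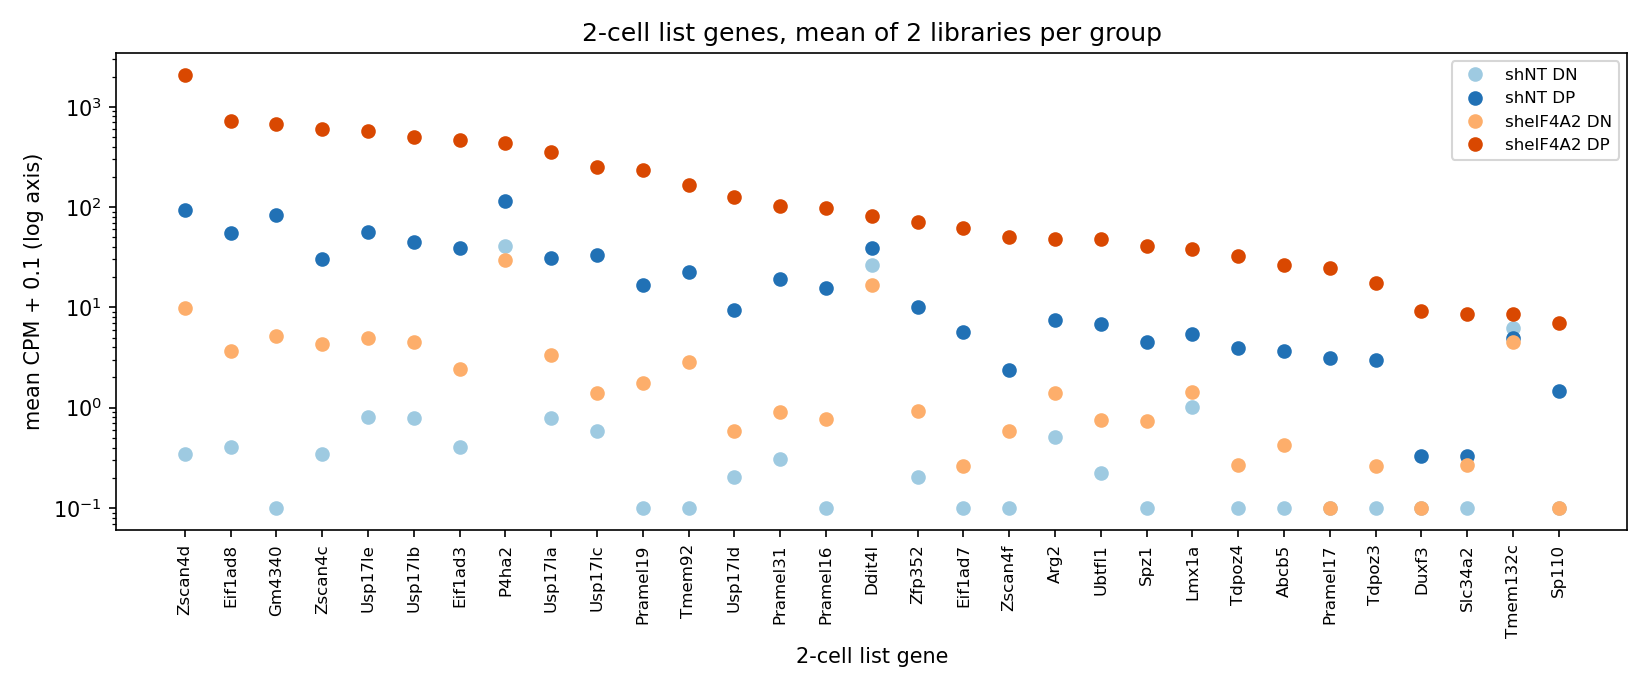
Mean CPM + 0.1 (log axis) of the measured genes of the 2-cell list in the 4 groups, each point the mean of 2 libraries. Zscan4d stood at 0.244, 9.67, 94.3 and 2088 CPM in shNT DN, sheIF4A2 DN, shNT DP and the DP libraries labelled sheIF4A2.

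Within DP cells, libraries labelled sheIF4A2 were compared with shNT, although Eif4a2 was called between them only with the trend in GC content and length removed. Zscan4d was 22.1-fold higher with sheIF4A2 (94.3 ± 3.41 against 2088 ± 8.21 CPM), Zscan4c 20.1-fold (to 605 ± 0.908 CPM), and Zscan4f and Pramel24 22.3-fold and 21.9-fold. Mecom, a zinc finger transcription factor gene, rose 16.6-fold, from 4.14 ± 1.68 to 68.8 ± 0.334 CPM. Of 31 2-cell genes 30 were higher, 0 lower and 1 not called in both adjustments, with a median of 2.90. The list test returned adjusted p = 1.47e-29, and adjusted p = 0.00742 with an estimated correlation. The largest falls were in Catip, from 42.7 ± 0.744 to 5.07 ± 0.489 CPM (-2.85 ± 0.27), Trim66 (-2.53 ± 0.46), Fat2 (-2.51 ± 0.32), Slc11a1 (-2.49 ± 0.28) and Zmynd10 (-2.45 ± 0.43).

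Naive pluripotency genes were mostly lower in the DP libraries labelled sheIF4A2, 19 of 30 with 4 higher (20 and 5 adjusted over the list alone). Tfcp2l1, a transcription factor of the naive state, went from 1322 ± 13.4 to 705 ± 8.85 CPM (-0.91 ± 0.05), and Tet2 and Tet1 fell by 1.07 ± 0.07 and 0.66 ± 0.05, whereas Fbxo15 rose by 2.20 ± 0.13. As a group they had adjusted p = 1.85e-05, and adjusted p = 0.0539 with an estimated correlation. Glycolysis genes were lower in 11 of 20 and higher in 2 (12 and 2 adjusted over the list alone), with Gpi1 at -1.04 ± 0.07 and Pfkp down, at -0.73 ± 0.07, and Slc2a3 up by 0.79 ± 0.04. Camera gave adjusted p = 1.42e-04, and adjusted p = 0.154 with an estimated correlation. Replication histones were higher in 8 of 21 and lower in 1 (11 and 1 adjusted over the list alone), H1f2 from 45.1 ± 4.21 to 131 ± 2.29 CPM. For the list as a whole, adjusted p = 0.00817, and adjusted p = 0.154 with an estimated correlation. Of 76 ribosomal protein genes 15 were higher and 2 lower in both adjustments, Rplp0 by 1.02 ± 0.14 and Rpl8 by -0.38 ± 0.06. By camera the group had adjusted p = 0.0274, and adjusted p = 0.233 with an estimated correlation. Given the small share of reads on these genes, the rise is uncertain as a change of level. Ribosomal protein genes were not called as a list without shNT DP replicate 1 (adjusted p = 0.0519) or with the trend in GC content and length removed (0.173). Mga was lower again (958 ± 6.61 against 418 ± 21.3 CPM, -1.20 ± 0.05), while the corepressor Trim28 was higher by 0.68 ± 0.06; in their list 7 rose and 4 fell of 27 in both adjustments.

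Smaller or mixed groups in DP were as follows. Initiation factors had 9 up and 3 down of 24 (10 and 3 adjusted over the list alone), with Eif4g2 up from 832 ± 27.9 to 1327 ± 14.3 CPM and Eif4b at -0.45 ± 0.06. The H3.3 and chaperone list had 4 up and 4 down of 14 (5 and 4 adjusted over the list alone), Dek at -0.67 ± 0.08 and Asf1b at 0.58 ± 0.13. In the germline list 5 of 19 rose and 1 fell, with Tex19.1 at 77.8 ± 3.94 and 278 ± 16.3 CPM (list adjusted p = 0.153). Feeder markers were higher in 3 of 9 and lower in 1: Thy1 stood at 24.5 ± 4.53 and 46.8 ± 2.17 CPM, and Fn1, the most abundant of them, at 623 ± 5.68 and 475 ± 20.4 CPM. Counts risen and fallen were 3 and 5 of 14 formative, 4 and 3 of 17 extraembryonic endoderm, 1 and 1 of 13 mesoderm, 2 and 0 of 12 neuroectoderm, 1 and 3 of 15 trophoblast, 6 and 5 of 23 integrated stress, 4 and 7 of 20 p53 target, 0 and 1 of 9 interferon and 4 and 7 of 25 cell cycle genes. Adjusted over the list alone they differed for formative (4 and 5), integrated stress (6 and 6), p53 target (4 and 8), germline (6 and 2) and cell cycle genes (6 and 7). Median and mean differed in sign for formative, trophoblast, integrated stress and interferon genes, as for trophoblast with 0.09 and -0.22. Limma called 2595 genes higher and 2494 lower, with 1582 higher without replicate 1 and 1563 without replicate 2 of the DP libraries labelled sheIF4A2. The authors' table gave 2368 and 2296.

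DN cells, sorted as lacking reporter signal, show the knockdown, and here Eif4a2 itself was lower. Lefty1, an inhibitor of NODAL signalling, rose from 15.9 ± 1.44 to 97.9 ± 13.7 CPM (6.13-fold, 2.54 ± 0.16). Aqp3, an aquaporin, fell from 159 ± 8.96 to 37.0 ± 3.23 CPM (0.232-fold, -2.07 ± 0.12). Zscan4d rose from 0.244 ± 0.345 to 9.67 ± 0.397 CPM (a ratio of 43.2 from pooled reads, with a counting interval of 11.4 to 365) and Gm4340 from no read to 5.09 ± 0.389 CPM, at least 15.1-fold. Other large differences were rises in Mrc1 (2.28 ± 0.44) and the RNase P RNA gene Rpph1 (2.67 ± 0.45, not called when only the 4 DN libraries were fitted, adjusted p = 0.0723) and falls in Sec14l5 (-2.53 ± 0.45) and Lrrc31 (-2.26 ± 0.33). Of 31 2-cell genes, 10 rose, 2 fell and 19 did not pass in both adjustments (median 0.57; adjusted p = 8.25e-06, but adjusted p = 0.0757 with an estimated correlation). P4ha2 and Ddit4l, with more reads in shNT DN than Zscan4d, were lower with sheIF4A2. P4ha2 stood at 29.5 and 29.2 against 36.9 and 44.6 CPM, and Ddit4l at 16.4 and 16.8 against 26.6 and 26.7 CPM. Whether DP cells left among the sorted DN cells gave the rises was not tested.

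Glycolysis and p53 target genes fell with sheIF4A2 in DN. Of 20 glycolysis genes 11 fell and 0 rose (14 adjusted over the list alone), with Gpi1 going from 644 ± 57.1 to 319 ± 9.38 CPM (-1.01 ± 0.07), Aldoa from 633 ± 17.4 to 394 ± 2.91 CPM (-0.68 ± 0.06) and Aldoc down by the largest step (-1.43 ± 0.21) of the 4 members with the smallest p. The list test returned adjusted p = 7.88e-08, and adjusted p = 0.0757 with an estimated correlation. Of 20 p53 targets 11 fell and 0 rose (13 adjusted over the list alone), with Trp53inp1 at 942 ± 6.74 and 556 ± 23.2 CPM (-0.76 ± 0.05), Mdm2 at -0.59 ± 0.07 and Bbc3 at -0.93 ± 0.12. As a group they had adjusted p = 2.84e-08, and adjusted p = 0.0757 with an estimated correlation. Formative genes rose in 5 of 14 with 0 fallen (8 adjusted over the list alone), among them the DNA methyltransferases Dnmt3b (77.4 ± 11.5 to 190.2 ± 16.6 CPM, 1.29 ± 0.11) and Dnmt3a (0.88 ± 0.08), with adjusted p = 1.97e-04 and adjusted p = 0.151 with an estimated correlation. Naive pluripotency genes went both ways, 11 up and 9 down of 30 (12 and 10 adjusted over the list alone; list adjusted p = 0.735): Esrrb fell from 1792 ± 27.2 to 1158 ± 5.83 CPM and Tbx3 from 605 ± 12.6 to 308 ± 3.03 CPM, while Gbx2 rose from 40.2 ± 6.81 to 124 ± 2.66 CPM. Ribosomal protein genes rose in 13 of 76 and fell in 3 (13 and 4 adjusted over the list alone), such as Rps15a (0.92 ± 0.17) and Rpl5 (0.61 ± 0.13), with Rpl8 at -0.33 ± 0.06. Camera gave adjusted p = 0.00317, and adjusted p = 0.151 with an estimated correlation. With the trend in GC content and length removed, the ribosomal protein list had adjusted p = 0.0543, and the small share of reads on these genes leaves their level uncertain here too.

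Among the remaining DN groups, initiation factors had 8 up and 3 down of 24 (9 and 4 adjusted over the list alone), with Eif3b and Eif3c each at 0.46 (standard errors 0.07 and 0.09) beside the fall of Eif4a2. H3.3 and chaperone genes had 2 up and 3 down of 14 (4 and 3 adjusted over the list alone), with Dek at -0.53 ± 0.08. Of 27 repressors of the 2-cell state 3 rose, such as the nucleolin gene Ncl (1089 ± 4.90 to 1715 ± 66.7 CPM), and 1 fell, Mga (1265 ± 15.0 to 742 ± 20.8 CPM). H2ax fell from 715 ± 9.82 to 393 ± 37.5 CPM, in a histone list with 1 up and 2 down of 21 (list adjusted p = 0.201). Fn1 was the 1 called feeder marker of 9, lower at -0.39 ± 0.06. Counts risen and fallen were 2 and 2 of 17 extraembryonic endoderm, 0 and 0 of 13 mesoderm, 2 and 0 of 12 neuroectoderm, 1 and 3 of 15 trophoblast, 3 and 2 of 19 germline, 3 and 4 of 23 integrated stress, 1 and 0 of 9 interferon and 8 and 4 of 25 cell cycle genes. Adjusted over the list alone they differed for extraembryonic endoderm (4 and 2) and integrated stress genes (3 and 5). Median and mean differed in sign for these lists and for naive pluripotency, as for integrated stress with 0.12 and -0.06. In neuroectoderm both were negative (-0.14 and -0.10) while the test pointed up. Limma called 1441 genes higher and 1613 lower. Without shNT DN replicate 1 these were 843 and 901, without sheIF4A2 DN replicate 1 they were 836 and 1064, and without shNT DN replicate 2 the lower count was 973. The authors' table gave 1366 and 1484.

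The differences between sheIF4A2 and shNT in DP and in DN rest on separate libraries and overlapped. Higher in both were 695 genes and lower in both 919, where independent lists of these sizes would share 225 and 242, and 62 and 63 genes went in opposite directions. Across all 16631 genes, which are not independent replicates, Pearson's r of the log2 differences was 0.397.

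The interaction asks whether DP and DN cells differ by more with sheIF4A2 than with shNT. P4ha2 stood at 40.8 ± 5.48, 115 ± 0.386, 29.4 ± 0.253 and 433 ± 25.8 CPM in shNT DN, shNT DP, sheIF4A2 DN and the DP libraries labelled sheIF4A2, an interaction of 2.36 ± 0.16 (adjusted p = 2.16e-11), and Ddit4l, also of the 2-cell list, gave 1.69 ± 0.24. For 2-cell genes with almost no reads in DN, the value hung on the pseudocount. With 1 CPM added, 27 of 31 were higher and 0 lower (30 adjusted over the list alone), with a median of 2.16 (adjusted p = 1.04e-24, and adjusted p = 0.0106 with an estimated correlation); with 5 CPM added, 30 were higher and 0 lower, with a median of 2.13. With 0.1 CPM added, 2 were higher and 1 lower, with 5 negative and a median of 1.29, though the list was still called (adjusted p = 0.00357), and with edgeR on reads, 2 were higher and 1 lower, with 8 negative and a median of 0.65. Zscan4d gave 1.33 ± 0.24 with 1 CPM and -0.86 with 0.1 CPM, and was not called without replicate 1 or 2 of the DP libraries labelled sheIF4A2 (adjusted p = 0.0570 and 0.0556). On the scale of levels the rise in DP was larger with sheIF4A2, whereas a difference in fold depended on these settings for most single genes.

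Other groups differed in the interaction as well. Naive pluripotency genes were lower in 12 and higher in 5 of 30 (15 and 5 adjusted over the list alone), with Utf1 at -1.01 ± 0.08 and Tet1 at -0.80 ± 0.07. For the list as a whole, adjusted p = 2.98e-05, and adjusted p = 0.0428 with an estimated correlation. Replication histones were higher in 6 and lower in 0 of 21 (10 adjusted over the list alone), H1f2 at 1.66 ± 0.19 and H2ax at 0.57 ± 0.09. By camera the group had adjusted p = 2.8e-06, and adjusted p = 0.0428 with an estimated correlation. Formative genes were lower in 8 and higher in 1 of 14 in both adjustments, Foxd3 at -1.50 ± 0.23. The list test returned adjusted p = 1.52e-04, and adjusted p = 0.125 with an estimated correlation. P53 targets were higher in 7 and lower in 0 of 20 (7 and 1 adjusted over the list alone), Pmaip1 at 1.46 ± 0.15. As a group they had adjusted p = 2.98e-05, and adjusted p = 0.0974 with an estimated correlation. Cell cycle genes were higher in 1 and lower in 2 of 25 (1 and 6 adjusted over the list alone; adjusted p = 0.00978, and adjusted p = 0.125 with an estimated correlation), with Ccnd3 at -0.52 ± 0.11. Slc2a3 gave 0.95 ± 0.06 and Dazl 1.51 ± 0.16. The feeder markers Fbn1 (adjusted p = 0.0348), Col1a2 (2.13 ± 0.69, adjusted p = 0.0427) and Thy1 (0.99 ± 0.32, adjusted p = 0.0431) were the 3 called of 9, and each call was lost with limma-voom and with edgeR. Counts higher and lower were 0 and 1 of 17 extraembryonic endoderm, 1 and 1 of 13 mesoderm, 1 and 1 of 12 neuroectoderm, 0 and 1 of 15 trophoblast, 1 and 0 of 19 germline, 4 and 1 of 24 initiation, 2 and 2 of 14 H3.3 and chaperone, 4 and 3 of 27 repressor, 4 and 2 of 23 integrated stress, 0 and 0 of 9 interferon, 1 and 2 of 76 ribosomal protein and 3 and 2 of 20 glycolysis genes. Adjusted over the list alone they differed for extraembryonic endoderm (1 and 1), initiation (5 and 2), H3.3 (3 and 3), repressor (4 and 5), integrated stress (6 and 3), ribosomal protein (0 and 0) and glycolysis genes (4 and 3). Median and mean differed in sign for extraembryonic endoderm, trophoblast, initiation, H3.3, repressor and ribosomal protein genes, as for initiation factors with -0.07 and 0.08. For glycolysis both were negative (-0.06 and -0.02) while the test pointed up. Limma called 962 genes higher and 826 lower. Without replicate 1 or 2 of the DP libraries labelled sheIF4A2 these were 394 and 371 or 392 and 387, without shNT DP replicate 2 they were 616 and 477, without shNT DN replicate 1 they were 591 and 464, and without shNT DN replicate 2 the lower count was 540.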

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

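Of the tests in this part, the wrong label, GC content and both state tests of Eif4a2 and the read total and multi-copy tests of the 2-cell genes were chosen after the result had been seen. The values in the next paragraph were picked out because the difference between sheIF4A2 and shNT was not the same in DP as in DN, by the interaction term of limma, and the last pattern was taken from the overlap of calls.

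The interaction called 962 genes higher and 826 lower. By list, the median log2 interaction was 2.16 for 2-cell genes, -0.28 for naive pluripotency, -0.49 for formative and primed genes, 0.21 for p53 targets, -0.13 for cell cycle genes and 0.94 for replication histones. With an estimated correlation the formative (adjusted p = 0.125), p53 target (0.0974) and cell cycle lists (0.125) were no longer called, and the 2-cell median was 1.29 with a pseudocount of 0.1, 2.13 with 5 and 0.65 with edgeR. By gene it was 0.62 for Eif4a2 and 0.38 for H3f3b. The largest positive values were 3.46 for Zscan4f, 3.42 for Gm4302, 3.41 for Antxr1, 3.38 for Gm11292 and 3.37 for Pcdh17, and those of Zscan4f, Gm4302 and Gm11292 were not past the threshold with 0.1 CPM as pseudocount. The largest negative values were -2.72 for Has2, -2.63 for Podnl1, -2.43 for Calhm5, -2.29 for Tpm2 and -2.29 for Hint3, all of low transcripts, and Has2, Calhm5, Tpm2 and Hint3 each lost the call when single libraries were left out.

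Eif4a2 was lower in the DN but not in the DP libraries labelled sheIF4A2. A trend with GC content or transcript length is argued against as the whole cause, since the interaction stayed at 0.42 ± 0.07 (adjusted p = 1.49e-04) once it was removed, although a fall of Eif4a2 in DP to -0.24 then passed the threshold. Control cells under a wrong label in DP that otherwise matched shNT DP would leave the genes called in DN without a shared direction. Such cells are argued against as the whole cause, since 83.6% of 3041 such genes kept theirs in DP. The 95% interval of 82.2 to 84.9% treats genes as independent. The median size was 0.39 against 0.60 in DN, where the genes were picked. A difference in preparation between the shRNAs, of which the labels say nothing, would give the same. So would control cells with a stronger 2-cell programme, if the genes called in DN move with it. A wrong label together with either stays open. A transcript higher in DP by the same step with either shRNA would give no interaction. The steps from DN to DP were 0.14 ± 0.05 in shNT and 0.76 ± 0.05 in sheIF4A2. Their difference is the interaction by which Eif4a2 was picked out, so this is no separate test. A transcript that rises with the 2-cell programme stays open. The excess of Eif4a2 in DP over DN, shNT relative to sheIF4A2, was 0.224 ± 0.0605 against 0.0453 to 0.193 for 2-cell genes.

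The 2-cell genes were higher in the DP libraries labelled sheIF4A2 than in shNT DP. A lower share of 2-cell-like cells in sorted shNT DP would give 1 ratio of the excess over DN, shNT relative to sheIF4A2. Over 27 genes with at least 100 reads in the DP libraries labelled sheIF4A2, its median was 0.122. It ran from 0.0453 ± 0.00284 for Zscan4d to 0.193 ± 0.0722 for Ddit4l. Gm4340, like Zscan4d almost without reads in shNT DN, gave 0.124 ± 0.00854. The chi-square was 10.9 per degree of freedom (p = 2.61e-45, treating genes as independent). Over these 27 genes, the values argue against such a share as the whole cause. The lowest ratios, however, were of multi-copy families, whose counts are less certain. Outside of multi-copy families and predicted genes, the ratios ran from 0.109 ± 0.0326 for Spz1 to 0.193 ± 0.0722 for Ddit4l. A single share was not tested on these members alone and is not argued against for them. A difference in read totals is argued against by the median of 2.90 over 31 genes after thinning (standard error over genes 0.15), and reads shared within multi-copy families by the median of 2.61 over the 12 members outside of them (from 0.72 for Tmem132c to 3.002 for Spz1), of which 11 were called. A difference in purity could still carry part of the change, beside a stronger 2-cell programme per cell, which the design does not separate. The sort gates and a preparation difference between the shRNAs stay open.

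Many genes moved the same way with sheIF4A2 in DP and in DN. Calls in DP and in DN share the estimated spread of each gene, so independent lists are a loose reference. The 1614 shared calls were 3.46 times those of independent lists, and 3.33 times with the trend in GC content and length removed (1563 against 470), so that this trend is argued against as the whole cause. After thinning to equal read totals the ratio was 3.94 (1365 against 346, over 17109 genes), which argues against read totals in the same way, though the number of genes with few reads was not matched. An effect of the hairpin, on Eif4a2 or elsewhere, and a difference in library preparation between shNT and sheIF4A2 cannot be told apart, because no shRNA was prepared in more than 1 known way and the labels do not name more than 1 hairpin against Eif4a2.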

How the results depend on the processing

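Of the alternatives, edgeR without and with the replicate block, thinning of reads and the removal of the trend in GC content and length were chosen after seeing the data. The others were planned, among them filterByExpr, the filter that the design had named for edgeR. Over all alternatives, 9217 values of named genes kept their side of the threshold, 780 lost their call, 54 gained one and 8 reversed. Direction was compared only where a call was made. The reversals were all in the interaction of Zscan4d and Gm4340, which were added there, with Zscan4c, after their values had been seen. Of the 780 lost calls, 193 fell to the limit of 1 log2 unit by construction. Of list tests 1673 were kept, 31 lost and 6 gained, of which 21 were lost with an estimated correlation. The 2-cell list in DN was one of these (0.57, adjusted p = 0.0757). The median of all genes was compared for DESeq2 size factors, library size only, thinning and GC and length removal. It moved by more than 0.1 only with the last, by -0.10 for DP against DN of sheIF4A2. For Eif4a2, a required difference of 1 log2 unit left 0.76 for DP against DN in sheIF4A2, -0.65 for sheIF4A2 in DN and 0.62 for the interaction short by construction, limma-voom passed 0.14 for DP against DN in shNT, and GC and length removal passed -0.24 for sheIF4A2 in DP; the cause of the last 2 was not tested.

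Counts that moved by over 1.5 times are given as higher and lower. For DP against DN in shNT they were 166 and 35 without a filter (21947 genes tested), 136 and 28 with only the 4 libraries compared, 117 and 12 at 1 log2 unit, and 601 and 312 with edgeR and a block; lower alone was 81 with DESeq2, 328 with limma-voom, 259 with edgeR, 88 after thinning and 238 after GC and length removal. For DP against DN in sheIF4A2 they were 1494 and 1251 with DESeq2 and 1121 and 327 at 1 log2 unit. For sheIF4A2 in DP they were 1029 and 691 at 1 log2 unit. For sheIF4A2 in DN they were 603 and 706 with only the 4 libraries compared and 234 and 338 at 1 log2 unit, with 1019 lower with DESeq2. For the interaction they were 494 and 507 with DESeq2, 589 and 422 without a filter and 489 and 211 at 1 log2 unit, with 1246 lower after GC and length removal. The 1 log2 limit and the smaller fits lower the counts by construction; for the rest the cause was not tested. The interaction of Zscan4d reversed to -0.97 with DESeq2, -0.93 with limma-voom, -0.86 with a pseudocount of 0.1, and -0.81 with edgeR without and -0.81 with a block; that of Gm4340 (0.40, not called) reversed to -2.68 with a pseudocount of 0.1, -4.29 with edgeR and -4.30 with the block, but was called at 1.93 with a pseudocount of 5 (adjusted p = 1.47e-07). These genes had almost no reads in shNT DN, and between pseudocounts their log ratio changed with the value added. For the reversals with DESeq2, limma-voom and edgeR the cause was not tested.

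With each library left out in turn, the lone library of its group being assumed to vary like the others, genes higher ran from 162 to 381 and lower from 25 to 165 for DP against DN in shNT, 1385 to 2343 and 1262 to 2014 in sheIF4A2, 1563 to 2595 and 1713 to 2512 for sheIF4A2 in DP, 836 to 1446 and 901 to 1536 in DN, and 392 to 809 and 371 to 626 for the interaction. The lowest counts came without shNT DP replicate 2, either sheIF4A2 DP library, sheIF4A2 DN replicate 1 or shNT DN replicate 1. Eif4a2 ran from 0.12 to 0.15 and 0.71 to 0.81 for DP against DN in shNT and sheIF4A2, -0.07 to 0.03 and -0.66 to -0.63 for sheIF4A2 in DP and DN, and 0.57 to 0.67 for the interaction. The 2-cell median ran from 2.73 to 3.18, 5.18 to 5.39, 2.75 to 3.14, 0.57 to 0.72 and 1.85 to 2.23 in the same order. Replicate differences were hardly correlated between groups (r of -0.0237 to 0.0341 over 10524 genes). Counting error adds to these differences, so whether samples of the same number were paired is not settled. A block on replicate numbers in limma gave 412 and 194 calls for DP against DN in shNT, against 367 and 158 without it. On simulated data with few changed genes, 1.5-fold changes were mostly missed at this depth. An absent call is no sign of an equal level.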

Other observations

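No test of an explanation is reported in this part, and its 4 gene lists were put together after the values had been seen. Hypoxia targets were lower with sheIF4A2 in DN cells, 11 of 24 with 0 higher (adjusted p = 7.14e-11 over the 4 lists, and adjusted p = 0.0257 with an estimated correlation). Bhlhe40, a transcriptional repressor, stood at 449 ± 19.5 CPM in shNT DN, 299 ± 8.70 in shNT DP, 147 ± 13.1 in sheIF4A2 DN and 67.6 ± 1.47 in the DP libraries labelled sheIF4A2. Ndrg1 (-1.84 ± 0.12), Bnip3 (-1.35 ± 0.09) and the growth factor gene Vegfa (-1.13 ± 0.08) were lower in DN as well. In DP, 10 were lower and 3 higher (adjusted p = 0.00220, but adjusted p = 0.104 with an estimated correlation). P4ha2 is in both the hypoxia and the 2-cell list.

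Targets of BMP and SMAD signalling were higher in DP than in DN, 3 of 9 in shNT (adjusted p = 3.92e-04, and adjusted p = 0.0377 with an estimated correlation) and 7 of 9 in sheIF4A2 (adjusted p = 4.09e-05, and adjusted p = 0.0426 with an estimated correlation). With sheIF4A2 they also rose in DP, 5 up and 1 down (adjusted p = 4.01e-04, but adjusted p = 0.0652 with an estimated correlation), and in DN, 4 up and 0 down (adjusted p = 0.0211, but adjusted p = 0.103 with an estimated correlation). Id3, an inhibitor of bHLH factors, stood at 5.64 ± 0.665, 12.8 ± 2.33, 21.8 ± 0.951 and 93.2 ± 0.532 CPM in shNT DN, shNT DP, sheIF4A2 DN and the DP libraries labelled sheIF4A2, and Id1 at 25.2 ± 2.98, 48.5 ± 2.36, 54.7 ± 3.88 and 157 ± 15.8 CPM. Of 8 NODAL targets, 3 rose and 0 fell in DP against DN of shNT, without any knockdown (adjusted p = 4.32e-05, and adjusted p = 0.0377 with an estimated correlation). With sheIF4A2 they were called in DN but not in DP (3 up and 2 down, adjusted p = 0.135). Their interaction was not called (adjusted p = 0.111, and adjusted p = 0.226 with an estimated correlation), so a difference between DP and DN is not shown. In DN 4 rose and 1 fell (adjusted p = 4.37e-04, and adjusted p = 0.0374 with an estimated correlation), with Nodal itself at 78.3 ± 4.97 and 125 ± 4.72 CPM beside Lefty1. Of 11 heat shock genes 6 rose in the DP libraries labelled sheIF4A2 against shNT DP (adjusted p = 5.62e-04, but adjusted p = 0.104 with an estimated correlation), with Hspa1a at 6.86 ± 1.54 and 47.8 ± 2.63 CPM and Hspa1b at 6.86 ± 2.17 and 54.4 ± 6.27 CPM. The list also rose with sheIF4A2 in DN, 4 genes up and 0 down (adjusted p = 0.00539, but adjusted p = 0.135 with an estimated correlation), and its interaction was not called (adjusted p = 0.111).

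The deposited table also compared groups that differ in both shRNA and subpopulation. The authors gave 2781 genes higher and 2680 lower for sheIF4A2 DP against shNT DN, and 1372 and 1639 for sheIF4A2 DN against shNT DP, at FDR under 0.05.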
